A study of Mus musculus with 6 samples.

How the data were processed

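The study measured gene expression in single mouse T cells by droplet sequencing (10x Genomics 3' chemistry, which counts unique molecular identifiers, UMIs, near the 3' end of each transcript). Per the labels' protocols, naive CD4 T cells from spleen were cultured for 48 h with human TGF-beta (3 ng/ml), IL-4 (20 ng/ml) and an antibody against interferon-gamma (20 ug/ml), conditions that drive T helper 9 (Th9) cells, which are named for the cytokine IL-9. There were 3 wild-type samples and 3 samples from mice lacking Cblb, the gene of the ubiquitin ligase CBL-B, a brake on T cell activation. Nothing in the labels states whether samples of a group came from separate mice or separate cultures, so p-values measure the spread between these samples, which may be technical.

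Per the submitters' processing notes, the tools were Cell Ranger 3.0.2 and Seurat 3.0.0 and the genome build was mm10. Their roles and settings are not given in the sources used here. The score values, 1 per gene and cell, are sctransform-corrected counts per the file headers, which the authors had adjusted to a common depth per cell before they were deposited. They are not raw counts, so no count model was used. The authors' table also holds the raw UMI count of each cell, which served to describe depth and to choose cells by depth for some alternatives. It also holds the percent of UMIs from mitochondrial genes, per the file headers. Cells had been filtered before deposit: the lowest raw total was 15006 UMIs and the highest mitochondrial share 15.2 percent. The authors' deposited cluster numbers, 0 to 6, were used as given. The 6 libraries are named in the table by sequencing index and genotype only, so they are called A, B and C (wild type) and D, E and F (knockout) here and have no replicate number. Their correlations across genes were below 1, and no library was counted as a copy of another.

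For each library the corrected counts were summed over cells and divided by the library's sum and multiplied by 1000000 (parts per 1000000, ppm). Genes with a mean of at least 5 ppm were tested with limma 3.58.1 (R 4.3.3) on log2(ppm + 1), with a trended prior variance, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(ppm + 1) scale and understate changes of low genes. Of 39 gene lists written before the data were examined, 38 had at least 5 tested members and were tested with limma's camera with an inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. The pattern for ribosomal proteins also matched ribosomal S6 kinases, which were removed. The named genes followed a rule of the same date: Cblb, Il9 and the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, without variable receptor segments, Y-linked, mitochondrial, ribosomal and unnamed genes. Design, lists and most of the other settings tried were fixed before the data were examined.

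On simulated data with the libraries' own spread, 8475 genes and 200 changed genes in each of 10 runs, the test recovered 55.8% of genes changed 1.25-fold, 89% at 1.5-fold, 97.6% at 2-fold and 100% at 4-fold. False calls made up 6.3% of calls, and runs with no change gave 0 calls. The noise was drawn independently for each gene, with the same spread in both groups. Real knockout libraries differed more among themselves (6.34 to 16.64 on the first principal component) than wild-type libraries (-13.26 to -12.22). Real genes also moved together, with an estimated correlation of 0.823 in the hypoxia list. These rates therefore do not measure the error of the real comparison.

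Cells were also clustered without integration on 2000 variable genes, 30 principal components and 15 neighbours (Leiden, resolution 0.5; scanpy 1.11.5, leidenalg 0.10.2). A cluster was named after a cell type only from markers fixed in advance. Genes were tested within every deposited or Leiden cluster with at least 50 cells in each library. Leiden clusters separated by genotype, so the deposited clusters lead within-cluster results; that choice was made after the data were seen. Shares of cells were compared with an exact two-sided permutation test of the 6 library values, for which 0.1 is the smallest possible p. Of the 16 genes compared in this way 1 is not reported here, nor are a few members of gene lists. Thinning to a fixed depth needs raw counts per gene, which were not used here; cells within 20% of the median raw total served instead. For the same reason no doublet caller was run, and doublets stay untreated. Cells with and without Il9 counts were compared within libraries by limma with the library as a block. Coordinates are from GENCODE M21 on mm10, on which 17134 of 17369 symbols had a single place; sequence similarity was searched with blastn 2.17.0.

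Alternatives included 3 scalings, pseudocounts of 0.1 and 10, other filters on low values, subsets of cells, other variance settings, sample weights and leaving out each library in turn. The fits with a replicate number as block were not run, and neither were DESeq2 and edgeR fits, which need raw counts.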

Results

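Th9 cultures of wild-type and Cblb-knockout CD4 T cells were profiled in 6 libraries, 3 of each genotype, with 27258 cells in all (12755 wild type and 14503 knockout). Libraries held 3902 (A), 4301 (B), 4552 (C), 3423 (D), 5666 (E) and 5414 (F) cells. Median raw depth per cell lay between 35573 UMIs in E and 39628 in D, and total depth between 149381789 UMIs in D and 229387950 in F. Median mitochondrial shares were 4.46% to 5.03%. On the ppm scale of corrected counts, the first principal component held 74% of the variance between libraries and placed the wild-type libraries between -13.26 and -12.22 and knockout libraries D, E and F at 16.64, 6.34 and 15.59.

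The first comparison asked whether the targeted gene and the cytokine that defines these cells differed between genotypes. Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048, plus strand, mm10) was 31.5 ± 0.91 ppm in wild type and 17.1 ± 1.85 ppm in knockout libraries (SD, n = 3 each), a log2 difference of -0.85 (SE 0.08, limma, Benjamini-Hochberg adjusted p = 0.000816). Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246, minus strand) rose from 227 ± 54.6 ppm to 721 ± 234 ppm, 3.10-fold, with a log2 difference of 1.63 (SE 0.27, limma, adjusted p = 0.0059). The share of cells with a Cblb value of at least 1 was 60.8% ± 1.10 in wild type and 41.5% ± 3.43 in knockout libraries (exact permutation test, two-sided, p = 0.1, the smallest possible). The labels do not describe the deleted part of Cblb, and 3' tags outside it would still be counted. Il9 stayed past the threshold under every alternative run, but its log2 difference was 0.69 when logarithms were averaged over cells.

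Over all cells, the largest rises among named genes in knockout libraries were those of the cytokine and chemokine genes Il13, Csf2 and Ccl22, and histone genes and Foxp3 were among the falls. Il13, a type 2 cytokine, was 1.69 ± 0.51 ppm in wild type and 71.8 ± 62.5 ppm in knockout libraries, 19.5-fold higher (limma, adjusted p = 0.00526). Its log2 difference was 4.28, 5.14 without library E and 3.57 without D. Csf2, which encodes GM-CSF, rose 13.1-fold from 0.76 ± 0.43 to 23.6 ± 12.7 ppm, and the chemokine gene Ccl22 rose 9.10-fold from 0.25 ± 0.03 to 10.7 ± 3.39 ppm (limma, adjusted p = 0.000722 and 0.000103). Foxp3, the transcription factor of regulatory T cells, fell by 1.13 on the log2 scale, from 14.9 ± 0.48 to 6.39 ± 1.98 ppm (limma, adjusted p = 0.00366).

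The other named genes that rose were Gatm (6.61-fold), Ly6a (4.75-fold), Cd70 (4.69-fold), Inhba (4.68-fold), Ntrk3 (4.59-fold), Sema4f (4.38-fold), Il1a (4.21-fold), Casz1 (4.02-fold) and Nr4a2 (3.91-fold). Cd70 encodes a TNF family ligand, Il1a an inflammatory cytokine and Nr4a2 a nuclear receptor induced by T cell receptor signals. The largest falls among named genes, as log2 differences, were those of Mndal (-1.95) and Trmo (-1.93), followed by Klf2 (-1.39), Hist1h2bj (-1.39), Trib2 (-1.32), Akr1c18 (-1.32), Nt5e (-1.23), Hist1h3a (-1.22), Apol9b (-1.13), Nsg2 (-1.12) and Hist1h1a (-1.11). Klf2 encodes a quiescence factor of resting T cells, and Nt5e the ectoenzyme CD73. Whether the strain background differs at Mndal and Trmo was not tested. Adjusted p for these 20 genes lay between 5.65e-05 (Trmo) and 0.0217 (Ly6a) in limma.

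**Figure D1:**
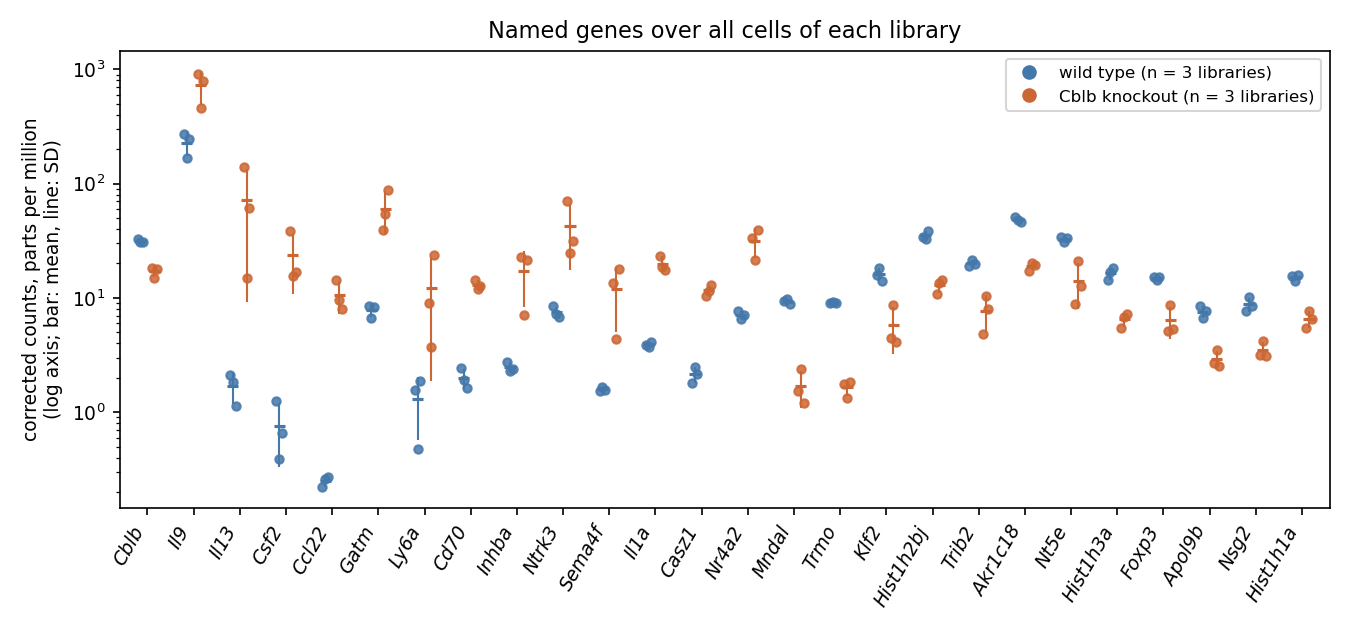
Corrected counts in ppm (log axis) of the 26 named genes in each library; points are libraries, bars means and lines SD, n = 3 per genotype. For every gene the 3 knockout libraries lie on the same side of the 3 wild-type libraries, as the naming rule requires beyond Cblb and Il9.

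In total 929 of 8475 genes were higher and 1139 lower in knockout libraries (limma, adjusted p under 0.05), of which 74 and 18 changed at least 2-fold. At an unadjusted p under 0.05 there were 3324 genes. The groups did not overlap for 3836 genes, 45.3% against 10% by chance. Without wild-type library A, B or C the counts were 459 higher and 408 lower, 442 and 442, and 396 and 381. Without knockout library E there were 1750 higher genes.

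Immune signalling lists were called higher by camera with the preset correlation, though another grouping of the libraries called 18 lists against 21 for the real one. Of 18 tested secreted cytokine genes 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 9.95e-05 and adjusted p = 0.292 with an estimated correlation), with Penk at a log2 difference of 1.77 beside Il13, Csf2, Ccl22 and Il9. Of 20 NF-kB genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 4.03e-06 and adjusted p = 0.292 with an estimated correlation), among them Traf1 (0.90), Bcl3 (0.82), Nfkb2 (0.76) and the inhibitor gene Nfkbia (0.55). Of 18 TNF family genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.45e-05 and adjusted p = 0.292 with an estimated correlation), with Cd70 (2.23), Fasl (1.06) and Tnfsf8 (0.94) as examples. Of 27 immediate early genes induced through the T cell receptor 11 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0085 and adjusted p = 0.326 with an estimated correlation), with Nr4a2 (1.97), Ier3 (1.55) and Fosl2 (1.40) rising most. Of 19 costimulatory and activation receptors 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0085 and adjusted p = 0.371 with an estimated correlation): Tnfrsf9 (0.66) and Tnfrsf4 (0.55) rose, Icos (-0.57) and Cd69 (-0.54) fell.

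Cytokine response lists were called higher as well. Among 18 IL-2 and STAT5 response genes 9 rose (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.59e-05 and adjusted p = 0.371 with an estimated correlation), including Gzmb (1.89), Socs3 (1.44), Socs1 (0.76) and Ccnd2 (0.56). Among 10 IL-4 and STAT6 response genes 6 rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00384 and adjusted p = 0.371 with an estimated correlation), including Ccl22 (3.19), Gfi1 (0.92), Socs1 (0.76) and Gata3 (0.41). Among 19 interferon-gamma-inducible GTPase and antigen presentation genes 10 rose (12 adjusted over the list alone, camera adjusted p = 4.03e-06 and adjusted p = 0.371 with an estimated correlation), including H2-Q7 (1.20) and H2-T23 (0.74), which encode nonclassical class I molecules. Among 13 type I interferon response genes 6 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0085 and adjusted p = 0.371 with an estimated correlation): Ly6a (2.25), Zbp1 (1.72) and Parp14 (0.57) rose and Ifi47 (-0.53) fell. Among 6 cytotoxic genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.0172 and adjusted p = 0.292 with an estimated correlation), Gzmb (1.89) and Fasl (1.06) most. Among 22 apoptosis regulators 7 rose and 3 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.0085 and adjusted p = 0.292 with an estimated correlation): Fasl (1.06), Bcl2a1b (0.54) and Cflar (0.51) rose and Bcl2l11 (-0.51) fell.

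Transcription factors of Th9 cells moved in both directions, more of them upward. Of 16 tested, 8 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0262 and adjusted p = 0.474 with an estimated correlation): Batf3 (0.97), Batf (0.81) and Bhlhe40 (0.69) rose and Irf8 (-0.58) fell. The 3 tested genes of the Th9 cytokine list, Il9, Ccl20 and Ccl22, all rose, too few for a list test. Of 7 Th2 genes Il13 (4.28), Gata3 (0.41) and Ccr8 (0.38) rose, 3 in all (4 adjusted over the list alone, camera adjusted p = 0.0304 and adjusted p = 0.465 with an estimated correlation). Of 21 amino acid transport and ATF4 target genes 7 rose (8 adjusted over the list alone, camera adjusted p = 0.000191 and adjusted p = 0.474 with an estimated correlation), with Asns (1.11) and Atf5 (0.76) rising most. Of 16 hypoxia genes 5 rose (6 adjusted over the list alone, camera adjusted p = 0.00127 and adjusted p = 0.556 with an estimated correlation), including Ndrg1 (0.83), Ddit4 (0.64), Vegfa (0.59) and Hif1a (0.59). A Leiden cluster led by Mt1, Bnip3, H2-Ab1, Slc16a3 and Il13, with the highest values of the hypoxia list, held 24.1% of the cells of library D, 19.9% of F, 2.49% of E and 0.30% to 0.37% of wild-type libraries. Without its cells the hypoxia list had a camera adjusted p of 0.353 and the Th2 list of 0.0706 (0.0907 without library F), and Il9, Il13 and Csf2 stayed past the threshold. The cluster was picked by the hypoxia list and is led in part by Il13, so the loss of these list calls is no independent evidence.

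The lists of respiratory chain, histone, MYC, unfolded protein response and S phase genes were called lower, and the list of ribosomal proteins higher. Of 55 nuclear-encoded respiratory chain genes 22 fell and 1 rose (27 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.54e-06 and adjusted p = 0.292 with an estimated correlation), by small amounts such as -0.37 for Ndufb2 and -0.34 for Cox7b. Of 11 replication-dependent histone genes 8 fell (10 adjusted over the list alone, camera adjusted p = 9.93e-06 and adjusted p = 0.292 with an estimated correlation), including Hist1h1a (-1.11) and Hist1h3c (-0.94). Of 32 MYC and ribosome biogenesis genes 10 fell (11 adjusted over the list alone, camera adjusted p = 5.66e-05 and adjusted p = 0.371 with an estimated correlation), led by Nme1 (-0.42). Of 18 unfolded protein response genes 10 fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00254 and adjusted p = 0.474 with an estimated correlation), including the chaperone genes Sdf2l1 (-0.60), Pdia3 (-0.59) and Pdia6 (-0.45). Of 42 S phase genes 6 fell and 1, Ccne2 (0.34), rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.0287 and adjusted p = 0.474 with an estimated correlation). Of 79 ribosomal protein genes 2 rose and 2 fell (0 and 1 adjusted over the list alone), and the list was called higher (camera adjusted p = 0.0166, adjusted p = 0.725 with an estimated correlation). Its adjusted p was 0.140 with TMM scaling and 0.110 with median-of-ratios scaling, 0.0811 without library A and 0.919 without E. The S phase list did not pass without C (0.0563), D (0.0968) or F (0.0998).

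**Figure D2:**
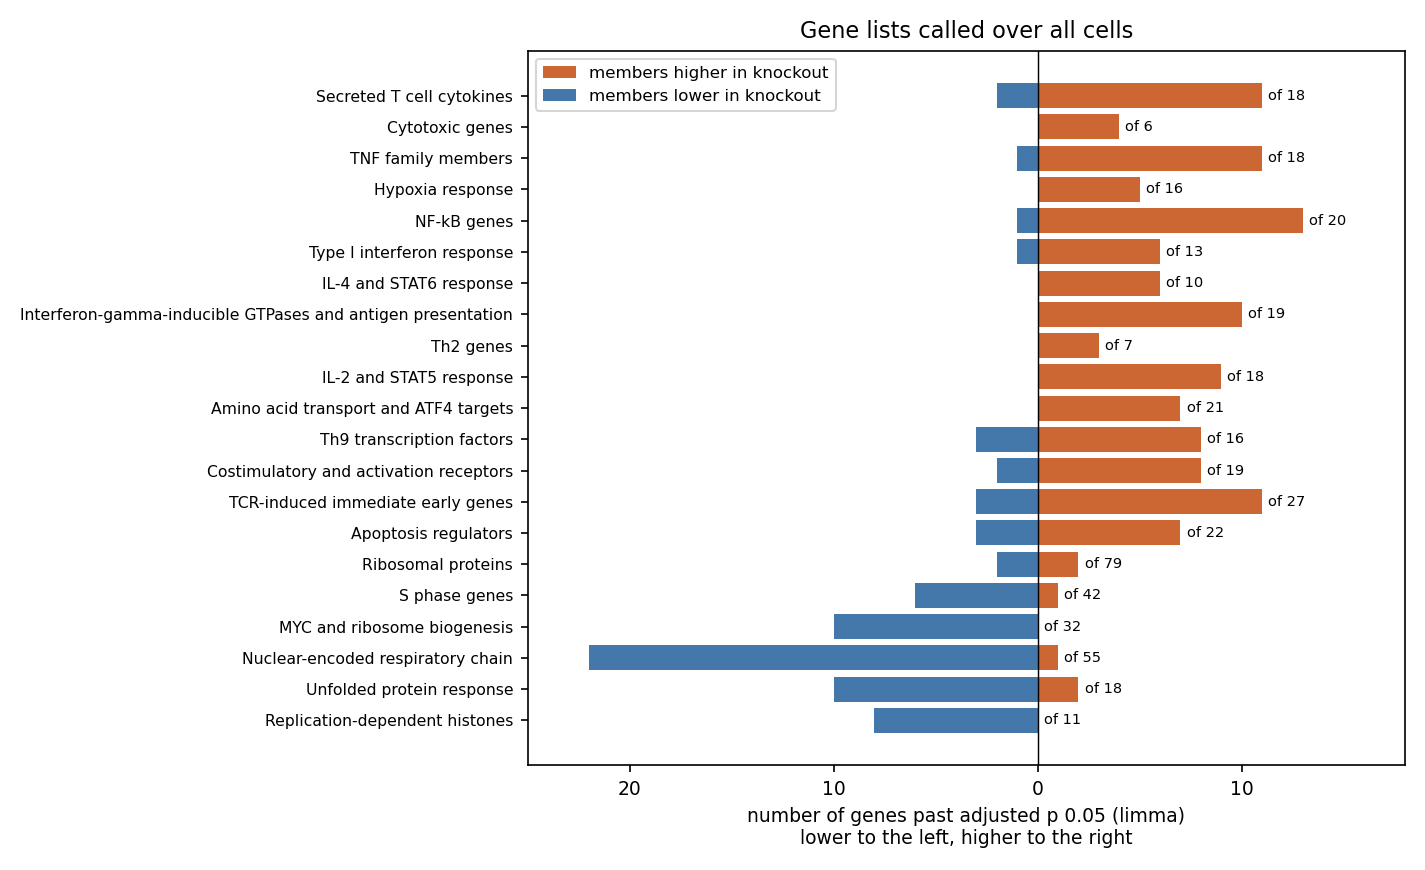
Members higher (right) or lower (left) in knockout libraries past adjusted p 0.05 in limma, for the 21 lists called by camera with a preset correlation; the number of tested members stands beside each bar. The respiratory chain list has the most lower members, 22 of 55, and the NF-kB list the most higher ones, 13 of 20.

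In all, 16 of 38 lists were called higher and 5 lower, and none was called with an estimated correlation. Another grouping of the libraries called 18 lists, so the number of called lists hardly separates the genotypes. In fry the hypoxia (adjusted p = 0.201), ATF4 (0.139), ribosomal protein (0.443), Th2 (0.0737) and Th9 factor (0.0737) lists did not pass. Nor did the type I interferon (0.0584) and unfolded protein response (0.0579) lists, while the other called lists passed. Among the 17 lists not called, Th1 genes came closest (8 tested, 5 higher and 2 lower, camera adjusted p = 0.0691), with Stat4 (1.01) higher and Ccl4 (-0.76) and Ctsw (-0.75) lower, and that list was called higher without library D (0.0307) and with TMM scaling (0.0251). Among 12 Treg genes 4 rose and 3 fell (5 and 4 adjusted over the list alone): Foxp3 (-1.13) and Capg (-0.54) fell, Tnfrsf9 (0.66) and Ctla4 (0.64) rose. Among 11 inhibitory receptor genes 5 rose and 4 fell (5 and 5 adjusted over the list alone), Ctla4 (0.64) and Lag3 (0.53) among the first and Nt5e (-1.23) and Tox (-0.87) among the second. Among 33 genes of proximal T cell receptor signalling 2 rose and 8 fell (2 and 10 adjusted over the list alone), and Themis (0.59) was among those that rose. The median, mean and camera direction differed in sign for Th17 genes (-0.14, 0.27, higher), Tfh genes (0.04, -0.08, lower), actin genes (-0.06, 0.13, lower), inhibitory receptors (0.02, -0.08, higher) and G2 and M genes (-0.001, -0.001, higher).

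Shares of cells with high values showed in how many cells a gene was abundant. Cells with an Il9 value of at least 10 made up 13.3% ± 2.55 of wild-type and 24.8% ± 5.08 of knockout libraries, and in those cells the mean Il9 value was 59.0 ± 4.3 and 103.7 ± 16 (SD, n = 3, exact permutation test, two-sided, p = 0.1). They held 89.3% to 97.0% of a library's Il9 counts. In the mast cell-like cluster described below 0% of 6 wild-type and 5.56% of 18 knockout cells reached this Il9 value, and in cluster 4 1.37% and 2.02%. At the same minimum the shares were 0.162% ± 0.095 and 4.71% ± 3.46 for Il13, 0.048% ± 0.042 and 2.12% ± 1.29 for Csf2, 2.91% ± 0.507 and 6.43% ± 0.382 for Ccl20, 12.3% ± 0.921 and 6.27% ± 0.857 for Ccl4, and 5.59% ± 0.248 and 2.25% ± 0.125 for Akr1c18. Library D carried 2 of these differences: in percentage points that of Il13 was 4.55 and 2.71 without D, and that of Csf2 2.07 and 1.34 without D. In cluster 3, described below, 91.3% of 1127 wild-type and 96.0% of 375 knockout cells reached 10 for Ccl4. Knockout shares were lower in clusters 1, 2, 4 and 5. In cluster 5, 82.1% of 859 and 88.3% of 350 cells reached 10 for Akr1c18. Cluster sizes were not compared, so these 2 falls over all cells are not read as lower expression per cell. For Il13, Csf2, Ccl20, Ccl4 and Akr1c18, 0 of 6 and 0 of 18 mast cell-like cells reached 10, which allows up to 50% and 16.7%. So few cells set no useful background for these genes. This minimum and its repeats without a library were chosen after the data were seen.

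**Figure D3:**
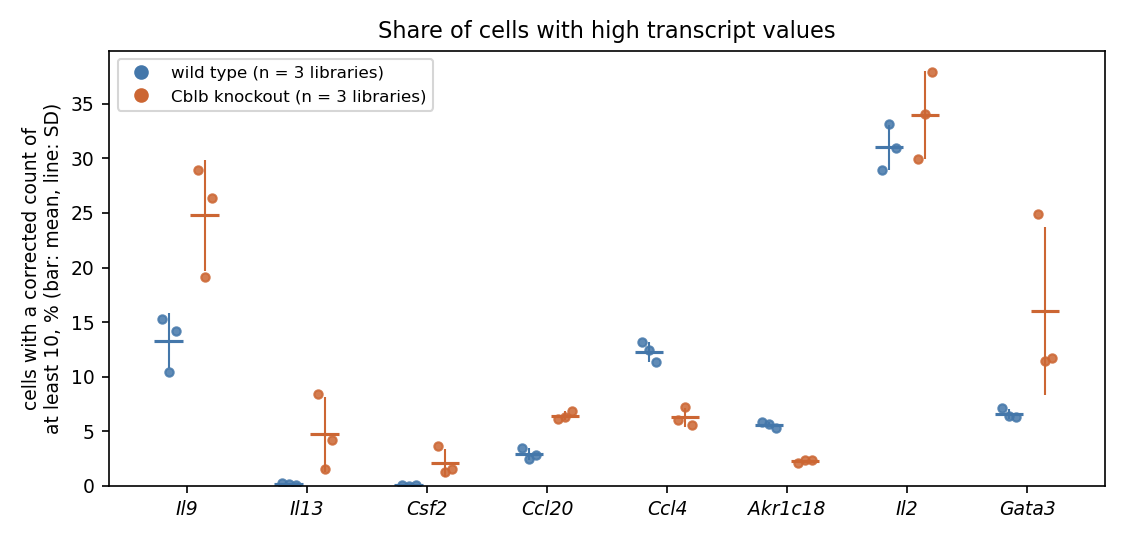
Share of cells (%) with a corrected count of at least 10 for 8 genes; points are libraries, bars means and lines SD, n = 3 per genotype. For Il9 the wild-type mean is 13.3% and the knockout mean 24.8%, while the libraries of both groups overlap for Il2.

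At the planned minimum of 1, shares in wild-type and knockout libraries were 46.2% ± 4.67 and 74.6% ± 11.7 for Il9, 1.06% ± 0.118 and 23.6% ± 13.6 for Il13, and 23.8% ± 0.578 and 11% ± 3.20 for Foxp3 (SD, n = 3, exact permutation test, two-sided, p = 0.1, Benjamini-Hochberg 0.178 over 16 genes). In the mast cell-like cluster described below, Il9 reached 1 in 83.3% of 6 wild-type and 88.9% of 18 knockout cells, Il13 in 16.7% and 27.8%, and Foxp3 in 0 of 6 and 0 of 18, which allows up to 50% and 16.7%. Median depths in that cluster were 27389 and 24759 UMIs. The mean Il9 and Il13 shares of both genotypes lay below those of the mast cell-like cells, but Il13 reached 34.3% in D and 28.2% in F. So few cells give no firm background, and the Il9 and Il13 shares are not read as expressing cells. For Foxp3 so few cells cannot decide, and its shares are not read as expressing cells either. The Foxp3 and Il9 shares did differ between cluster 1 and the deeper cluster 4. For Foxp3 they were 34.4% and 24.2% against 7.7% and 4.9%, and for Il9 54.3% and 81.5% against 22.7% and 57.3%. Median depths were 37090.5 and 35745.5 UMIs in cluster 1 and 41732 and 41693 UMIs in cluster 4. Mast cells can make Il9 and Il13 themselves, so the mast cell-like cluster may set their background too high. The lower Il9 shares in the deeper cluster 4 point the same way. Groups also did not overlap for Il5 (0.324% ± 0.089 and 2.73% ± 2.30), Il21 (0.094% ± 0.043 and 6.57% ± 8.32), Il24 (0.585% ± 0.20 and 3.21% ± 1.92), Tbx21 (2.83% ± 0.811 and 11% ± 4.61), Gata3 (92.8% ± 0.285 and 95.7% ± 1.29) and Irf4 (98.9% ± 0.025 and 98.7% ± 0.183). Single libraries carried 3 of these differences: in percentage points that of Il21 was 6.48 and 1.71 without F, that of Il5 2.40 and 1.13 without D, and that of Irf4 -0.169 and -0.066 without F. In the same 6 and 18 cells the shares were 0% and 5.6% for Il5, 66.7% and 72.2% for Gata3, 83.3% and 88.9% for Irf4, and 0 of 6 and 0 of 18 for Il21, Il24 and Tbx21. For Il21, Il24 and Tbx21 this again allows up to 50% and 16.7%, and Il5 was seen in 1 of 18 knockout cells. So few cells cannot decide, and the shares of these genes are not read as expressing cells either. Groups overlapped for Il2, Il4, Il10, Il17a, Ifng and Spi1.

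Cell composition was described with the deposited clusters. Leading genes were Tmem176a, Dapl1, Tmem176b and Il2 in cluster 0, Foxp3, Klf2 and Socs2 in cluster 1, Il9, Batf3 and Lta in cluster 2, Ccl4, Ccl3 and Ifng in cluster 3, Ccl20 and Il2 in cluster 4 and Akr1c18 in cluster 5. Cluster 6 was mast cell-like or basophil-like, with all 5 markers of that kind in the table (Mcpt8, Cpa3, Fcer1a, Ms4a2 and Gata2) at least 8 times higher than elsewhere, and held 24 cells. Sizes were not compared between genotypes, because 10, 8, 5, 6, 8 and 6 of the 10 leading genes of clusters 0 to 5 differed between genotypes within another cluster. Without integration, 94.1% of cells fell into Leiden clusters with over 80% of cells of 1 genotype, 7 of 12 clusters. No deposited cluster was of that kind.

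Within clusters the same cytokine genes had higher counts in knockout libraries. Il13 rose in each of the 6 clusters, by log2 differences of 2.58 (cluster 1) to 6.17 (cluster 3). Il13 averaged 0.33 and 0.56 per cell in the mast cell-like cluster of wild-type and knockout libraries, from 1 of 6 and 5 of 18 cells. Its knockout average lay below that value in cluster 1 (0.37) and above it in cluster 4 (0.84). Mast cells can make Il13 themselves, so this comparison cannot decide whether these low averages are free RNA. Il9 rose in 5 clusters: from 2904 ± 212 to 4006 ± 432 ppm in the Il9-led cluster 2 (log2 0.46), from 265 ± 85.5 to 1470 ± 290 ppm in cluster 5 (log2 2.49), and by 1.63, 1.13 and 1.36 in clusters 0, 1 and 4 (limma, largest adjusted p = 0.00637). In cluster 3 it was 51.3 ± 8 and 79.7 ± 25.4 ppm (adjusted p = 0.125). The mast cell-like cluster averaged 1.5 and 6.72 Il9 counts per cell. Clusters 0 (0.69 and 2.3) and 4 (0.6 and 1.58) lay below it in both genotypes. Cluster 1 (3.81 and 7.94) lay above it in wild type and near it in knockout libraries. Mast cells can make Il9 themselves, so these averages cannot tell expression from free RNA in clusters 0 and 4. Low Il9 counts there are not read as expression. Il9 values of at least 10 were found in 13.2% of wild-type and 26.8% of knockout cells of cluster 1. The shares were 1.51% and 4.72% in cluster 0 and 1.37% and 2.02% in cluster 4. Among mast cell-like cells such values were found in 0 of 6 and 1 of 18. Cluster 5 averaged 10.05 and 53.85. Il2 rose in cluster 3 (1.48) and cluster 4 (0.49) and did not pass in the others, and no test compared clusters. Cblb fell in all 6, between -0.98 and -0.73. Il17a (3.48) rose in cluster 4, Il3 (4.35) in cluster 3, and Ccl17 (2.87) and Il24 (2.15) in cluster 2, and Coro2a (-3.23) fell in cluster 2. In these clusters Il17a reached 1 in 1 of 365 wild-type and 14 of 893 knockout cells, Il3 in 15 of 1127 and 52 of 375, Ccl17 in 7 of 661 and 71 of 2055, and Il24 in 12 of 661 and 195 of 2055. Among knockout mast cell-like cells Ccl17 reached 1 in 2 of 18, and Il17a, Il3 and Il24 in 0 of 18, which allows up to 16.7%. By these few cells free RNA is not excluded as a source of these counts. Pooled over knockout cells, Il3 reached 1 in 13.9% of cluster 3 and 0.3% to 4.0% of clusters 0, 1, 2, 4 and 5. Il24 reached it in 9.5% of cluster 2 and 0.9% to 4.0% of clusters 0, 1, 3, 4 and 5. This argues against evenly spread free RNA as the sole source of Il3 and Il24, though libraries were not compared. Ccl17 (3.5% in cluster 2, 5.6% in cluster 3) and Il17a stay open.

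Genes called higher and lower numbered 770 and 1085 in cluster 0, 773 and 807 in cluster 1, 708 and 984 in cluster 2, 381 and 323 in cluster 3, 459 and 643 in cluster 4 and 413 and 394 in cluster 5 (limma). Of 8125 genes tested in all 6 clusters, 145 were higher and 142 lower in every cluster. Leaving out wild-type library C lowered each of these counts over 1.5 times, to 283 and 314, 382 and 286, 398 and 437, 131 and 55, 245 and 253 and 177 and 97 in the same order. The values for the other libraries stand with the processing alternatives. In Leiden clusters 2 and 6, with at least 50 cells in every library, 71 and 130 genes were higher and 126 and 86 lower.

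**Figure D4:**
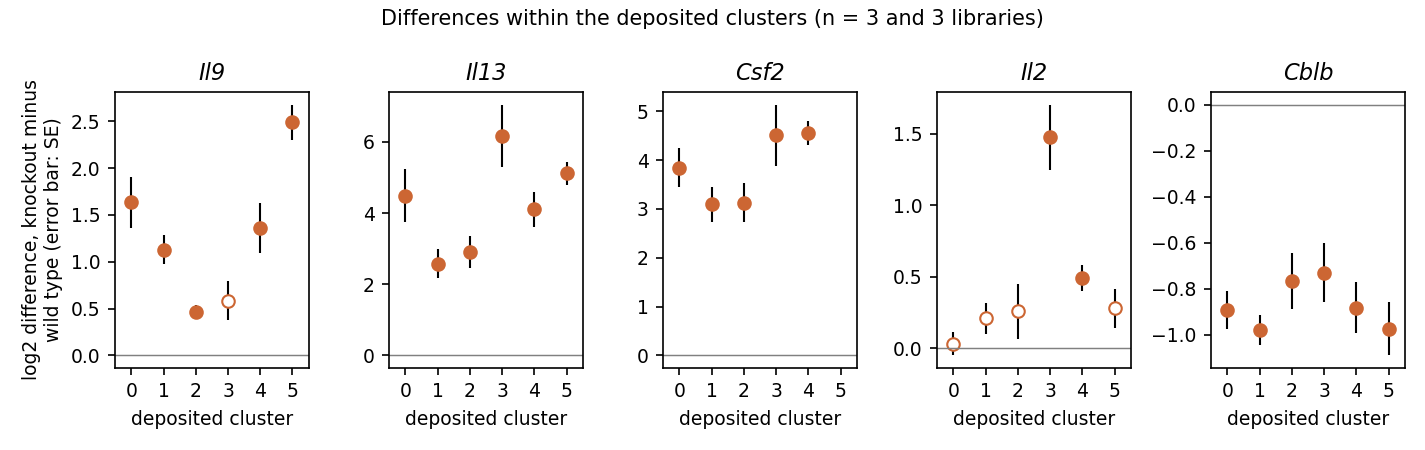
Log2 difference of knockout against wild type with SE for Il9, Il13, Csf2, Il2 and Cblb in deposited clusters 0 to 5 (n = 3 libraries each); filled points passed adjusted p 0.05 in limma. Csf2 was below the filter on low values in cluster 5, and Il9 did not pass in cluster 3.

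Cell cycle phases were compared because the cultures were dividing. The S phase share was 36.0% ± 0.715 in wild type and 31.5% ± 0.677 in knockout libraries, and the G2 and M share 62.2% ± 0.834 and 66.1% ± 1.71 (SD, n = 3, exact permutation test, two-sided, p = 0.1 each), and G1 was 1.77% and 2.33% (exact p = 0.5). Among 52 G2 and M genes 1, Top2a (0.19), rose and 3 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.889). The mean S score times 100 was 7.86 ± 0.448 and 6.50 ± 0.637 (exact p = 0.1), without overlap of the groups, and the mean G2 and M score times 100 was 20.1 ± 0.233 and 20.1 ± 1.07 (exact p = 1). Free RNA enters phase calls and scores too, so no difference in cycling is read from them.

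Cells with an Il9 value of at least 1 were compared with cells of value 0 in the same library. In the mast cell-like cluster 83.3% and 88.9% of wild-type and knockout cells reached 1 (median depths 27389 and 24759 UMIs). Mast cells can make Il9 themselves, so the background is not known, and the first class is not read as expressing cells. Batf3 (1.63), a transcription factor gene, Sgk1 (1.32), Lta (1.27), Nppc (1.05) and Socs2 (1.05), a target of STAT5, were higher in the first class, and so were Fcmr (0.99), Serpina3g (0.96), Ctla2a (0.92), Rragd (0.89), Atf3 (0.85), Gpr83 (0.75) and Foxp3 (0.74). Lower were the chemokine gene Ccl20 (-1.09), Kcnk10 (-0.90), Cib2 (-0.88), Csf1 (-0.88), Myh10 (-0.86), Cd5l (-0.86), Filip1l (-0.85), Il2 (-0.85), Klrb1f (-0.78), Ms4a4b (-0.78), Igfbp7 (-0.77) and Pou2af1 (-0.77). Each held in 6 of 6 libraries, with adjusted p of at most 8.25e-08 in limma (Cib2). In total 1625 of 8488 genes were higher and 3219 lower. The genotypes differed in this contrast for 487 genes, and for 1635 at an unadjusted p under 0.05. With Il9-negative cells matched on depth the number was 210. With values of at least 10 against at most 2, a contrast added after the data were seen, the log2 differences of Batf3 and Il2 were 2.44 and -1.46, and 0% and 5.56% of the mast cell-like cells reached 10.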

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

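The tests of genes around Cblb, of the low-oxygen cells, of other cell types and of Il9 shares between clusters were chosen after the result was seen; the ratio of Il13 to Il9 was planned before its values were known. Cells of another type stood out in cultures of purified CD4 T cells: the mast cell-like cluster held 24 cells, 6 wild type and 18 knockout.

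The contrast between cells with and without Il9 counts differed between genotypes, by an interaction test in limma, for 10 of the 24 named genes. As log2 differences, knockout minus wild type, the contrast was smaller in knockout libraries for Nppc (-0.82), Serpina3g (-0.61), Batf3 (-0.33) and Atf3 (-0.26) and larger for Socs2 (0.18). For genes lower in cells with Il9 counts it was closer to 0 in knockout libraries for Klrb1f (0.48), Cd5l (0.40), Filip1l (0.34), Myh10 (0.25) and Igfbp7 (0.25). Adjusted p for these lay between 0.000142 (Nppc) and 0.049 (Cd5l). The minimum of 1 may lie near background, since 83.3% of wild-type and 88.9% of knockout mast cell-like cells reached it. Mast cells can make Il9 themselves, however. In cluster 4 19.6% to 24.3% of cells reached 1 in wild-type libraries and 41.9% to 76.5% in knockout libraries. Cells with and without Il9 counts numbered 1802 and 2100 in A but 4705 and 709 in F. Free RNA that places more cells in the first class would bring contrasts closer to 0 in knockout libraries, the direction of 9 of these 10 genes, so it stays open as their source and was not tested. With Il9 values of at least 10 against at most 2 the interaction passed for 943 genes, with the same sign for Nppc (-0.82, adjusted p = 0.000406), Serpina3g (-0.89, 0.000213), Batf3 (-0.27, 0.00824), Atf3 (-0.29, 0.00772), Socs2 (0.49, 0.000128) and Klrb1f (0.31, 0.0498) in limma. It did not pass for Filip1l (0.16, adjusted p = 0.290), Myh10 (0.25, 0.237) and Cd5l (0.02, 0.929), and for Igfbp7 (-0.09, 0.564) it had the other sign and did not pass.

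Il9, Il13 and Csf2 were higher in all 3 knockout libraries. A low-oxygen state of many cells in D and F as the sole source is argued against, since without that cluster the smallest of the 3 log2 differences was 1.61 and the largest adjusted p 0.00463 (limma). Cells of another type are argued against in the same way, with 1.64 and 0.00579 after their removal. Among cells within 20% of the median raw total Il9 kept a log2 difference of 1.59 and passed in limma. An effect of genotype, which the design names, stays open as a hypothesis, and doublets and culture conditions were not tested.

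Genes called in the same direction in all 6 deposited clusters were more frequent around Cblb, where DNA of the donor strain may have been carried along with the targeted allele. Within 20 Mb they were 7 of 89 genes (7.9%) against 278 of 7971 elsewhere (3.5%), an odds ratio of 2.36 (Fisher's exact test, two-sided, p = 0.0376). The excess depends on the window: p was 0.458 for 5 Mb, with 1 of 17 genes, 0.0477 for 10 Mb and 0.0196 for 40 Mb. Genes called over all cells were 47.1% of those within 5 Mb, 46.2% within 10 Mb, 33.7% within 20 Mb and 29.5% within 40 Mb. Elsewhere they were 24.0%. Fisher's exact p for these was 0.0418, 0.00238, 0.0451 and 0.0702. The other 278 genes called in all 6 clusters lie outside the 20 Mb window, so this explanation covers at most a small part of the pattern. Strain differences elsewhere in the genome and an effect of CBL-B loss remain open and were not tested.

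Outside cluster 2 most knockout cells had 1 to 9 Il9 counts, which could come from free RNA. The test was limited to the knockout libraries after the values of all 6 were seen. The largest difference in the share of cells with Il9 between clusters 0, 3 and 4 was 11.3 percentage points in knockout library D, 14 in E (95% interval 5.2 to 22.8) and 7.1 in F, and no interval lay above the bound of 10, so free Il9 RNA is neither excluded nor shown. In wild-type libraries the differences were 16.1 in A, 12.5 in B and 21.9 in C (95% interval 12.7 to 31.1, above 10). In low cells of cluster 4, with at most 9 counts of each gene, the ratio of Il13 to Il9 counts was compared with the uncut whole library. It was 2.24, 5.04 and 3.08 times as high in D, E and F. The bound was 3 times, beyond the 95% interval. Only E passed it (0.116 to 0.224 against 0.032). D lay within the bound, and the interval of F (0.199 to 0.291 against 0.078) did not clear it. This argues against free RNA as the sole source of both genes at once in E only. The ratio leaves open free RNA as the source of the low Il9 counts, and low expression of Il9 in these cells is a hypothesis only.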

How the results depend on the processing

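Alternatives with the low-oxygen cluster left out, the window on raw totals, the minimum of 10, the deposited clusters, and other scalings for lists were added after the data were seen. No paired analysis was possible because the library names carry no replicate numbers, so fits with a replicate block were not run; fits on raw counts were not run either. Of 143 named genes, 93 kept direction and side of the threshold under all alternatives in which they were tested, and 121 when leaving out libraries is set aside; none reversed. The scalings moved the median of all genes to at most -0.046. Depth limits the low genes: shares near 0 rest on few counts.

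Counts for all cells moved with the filter (1433 higher with none, 547 at 20 ppm, where fewer genes were tested) and with sample weights (1404 higher). Without a library they ranged from 396 to 1750 higher and 381 to 1396 lower. With an estimated correlation 0 lists were called higher and 0 lower; without a library, 15 to 17 and 4 to 6. At 20 ppm the higher genes numbered 462 in cluster 0, 468 in cluster 1 and 270 in cluster 5. Interactions numbered 939 (Il9 of at least 2), 210 (depth matched) and 943 (at least 10 against at most 2). The share of cells in clusters of 1 genotype was 99.6% at resolution 0.3, 90.3% at 1.0, 93.5% with 15 components, 93.9% without cell cycle genes and 0% in deposited clusters. Except where fewer genes or samples were tested, the cause was not tested.

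Without a library, higher and lower genes ranged from 283 to 1399 and 314 to 1247 in cluster 0, 382 to 1144 and 286 to 914 in cluster 1, 398 to 850 and 437 to 894 in cluster 2, 125 to 899 and 55 to 666 in cluster 3, 237 to 578 and 253 to 624 in cluster 4, 177 to 627 and 97 to 516 in cluster 5, 18 to 65 and 34 to 100 in Leiden cluster 2, and 55 to 134 and 21 to 120 in Leiden cluster 6. Changes over 1.5 times, as higher and then lower genes, were these. Cluster 0: A 344 and 366, B 340 and 436, C 283 and 314, E 1399 higher. Cluster 1: A 395 and 287, B 436 and 346, C 382 and 286. Cluster 2: C 398 and 437, A 537 lower, B 620 lower. Cluster 3: A 125 and 57, B 142 and 80, C 131 and 55, D 227 and 203, E 899 and 666, F 246 higher. Cluster 4: A 284 and 285, C 245 and 253, D 237 and 285, B 412 lower. Cluster 5: A 200 and 113, B 186 and 126, C 177 and 97, E 627 higher. Leiden cluster 2: B 30 and 57, C 33 and 34, D 18 and 42, F 46 and 73, E 69 lower. Leiden cluster 6: A 75 and 21, B 58 and 24, C 55 and 21.

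Reversed directions, none of them past the threshold on either side, were found for lists, given as signed -log10 p. Inhibitory receptors: -1.23 in fry, -0.02 without D, -0.08 without E (highest 0.29, without F). G2 and M genes: -0.04 in fry, -0.01 with TMM, -0.06 without low-oxygen cells, -0.04 without B, -0.44 without D (highest 0.59, without F). Glycolysis: -0.56 without low-oxygen cells. p53 targets: -0.21 in fry, -0.29 without A, -0.08 without F (highest 0.34, without C). Heat shock: -0.07 without D (highest 0.46, without C). Actin: 0.02 with TMM, 0.02 without F (lowest -0.28, without D). Shares, in percentage points, reversed for Ifng (-0.002 without B, highest 0.191 without A) and G2 and M (-0.008 when at least 3 of 8 genes were required, a saturated measure). The causes were not tested.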

Other observations

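The tests of other groupings of the libraries were chosen after the result was seen; the test of Gm10093 and Hdac1 was planned before their sum was known, and the way it is read was settled afterwards.

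Some gene groups without a called list held strong single changes. Among 24 actin and adhesion genes 6 rose and 8 fell (7 and 9 adjusted over the list alone): Anxa2 (1.29), Lgals1 (1.11), Ahnak (1.10) and Lgals3 (0.98) rose most. Among 22 anergy genes and ubiquitin ligases 6 rose and 5 fell (6 and 6 adjusted over the list alone): Socs1 (0.76), Nedd4 (0.71) and Tnfaip3 (0.46) rose and Egr3 (-0.38) fell. Among 19 naive and quiescence genes 5 rose and 6 fell (7 and 6 adjusted over the list alone), with Satb1 (0.98), Dapl1 (0.84) and Il7r (0.80) rising against Klf2 (-1.39). Among 17 p53 targets 2 rose, Cdkn1a (1.24) and Plk2 (0.92), and 4 fell (3 and 5 adjusted over the list alone). Among 14 TGF-beta response genes 3 rose and 1 fell (4 and 1 adjusted over the list alone): Pmepa1 (0.76) rose and the receptor gene Tgfbr1 (-0.62) fell.

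Among 12 chemokine and homing receptors 3 rose, Gpr183 (0.73), Ccr7 (0.50) and Ccr8 (0.38), and 0 fell (3 and 2 adjusted over the list alone). Of 28 cholesterol and fatty acid synthesis genes 5 fell, Dhcr7 (-0.62) most (5 adjusted over the list alone). The list Cholesterol and fatty acid synthesis was called lower without B (camera adjusted p = 0.0171) and without D (0.00181). Of 19 glycolysis genes 1, Hk2 (0.74), rose (1 adjusted over the list alone), and the list was called higher without E (camera adjusted p = 8.05e-05). Of 13 mitochondrially encoded genes 3 rose, led by mt-Nd3 (0.60) (3 adjusted over the list alone). Of 16 heat shock and handling genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), Atf3 (0.91) and Fos (0.79) rising. Of 5 Th17 genes 2, Il1rn (1.82) and Rora (0.83), rose and Ahr (-0.80) fell (2 and 2 adjusted over the list alone). Of 7 Tfh genes Cd200 (0.48) rose, and Slamf6 (-0.59), Icos (-0.57) and Pdcd1 (-0.30) fell (1 and 3 adjusted over the list alone).

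Smaller Leiden clusters held 734 cells led by the p53 targets Phlda3, Cdkn1a and Ccng1, 65 cells led by Gm26870 and Ccl22 with a median mitochondrial share of 0.37%, 39 cells led by Gzmb and the gamma delta receptor genes Trdc and Tcrg-C2, and 16 cells led by Ptcra. The 39 cells also carried 4 of 5 NK or ILC markers and 5 of 7 Th1 markers and were left unnamed.

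Unnamed gene models were looked at after their values were seen. Gm42031 (chromosome 8, a lincRNA) was 68.5 ppm in wild type and 0.23 ppm in knockout libraries, and Gm10093 (chromosome 17, a processed pseudogene) 0.64 and 27.9 ppm. Gm10093 is 99.4% identical over 1444 bases to Hdac1, which was 146 and 93.8 ppm (log2 -0.67; limma, adjusted p = 0.0187), so reads may have been assigned to one copy or the other. Exchange alone would leave their sum within 0.1 of its wild-type level on the log2 scale; the sum differed by -0.278 (SE 0.106), beyond the bound written in advance. That bound took Hdac1 to change by exchange only, and Hdac1 was lower by 52.6 ppm where Gm10093 was higher by 27.3 ppm, so exchange together with a separate fall of Hdac1 is not excluded and the sources cannot be told apart here.

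With 3 libraries against 3 there are 10 groupings of equal size, too few for a share under 0.05; in each case 1 of the 10, the real one, gave a count as large. The real count and the highest other were 2068 and 0 genes for all cells, 1855 and 0, 1580 and 0, 1692 and 0, 704 and 0, 1102 and 1 and 807 and 0 for clusters 0 to 5, 197 and 1 for Leiden cluster 2, 216 and 0 for Leiden cluster 6, and 21 and 18 for lists. For cells with and without Il9 counts, 1 of 32 swaps of the classes within libraries, the real one, reached 4844 genes. The highest other was 487, the same number as the genes for which the genotypes differed in this contrast. Chance labelling of the classes is excluded at 0.05. The classes were cut on Il9 in these same cells, so the test does not tell why they differ.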
